A study of Rattus norvegicus with 20 samples.

How the data were processed

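RNA was measured in the nucleus accumbens, a ventral striatal region of the brain reward circuit, of male Sprague-Dawley rats that self-administered cocaine. Per the labels' protocols, the rats were housed 2 to a cage and drank their assigned solution freely. The labels give RNA extraction with an RNeasy column kit, cDNA made with a SMARTer kit and polyA RNA as the molecule. The authors deposited 1 table of counts per gene symbol for 20 libraries, with whole numbers that sum to different totals in each library. Per the submitters' processing notes, FastQC 0.11.6, STAR 2.4.0, limma and the build Rnor_6.0 were used. The counting tool, the gene annotation, the strand setting and any trimming are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be assigned with certainty.

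The table holds 17296 symbols, of which 1822 were at 0 in every library. In a RefSeq table of the GRCr8 assembly, 15156 of the symbols are current and 16952 are current or listed as synonyms. That table was used for names and gene neighbours only, and no coordinates are given because its assembly differs from the authors' build. The counts of 6 pairs of symbols were identical in all libraries, among them Cers1 with Gdf1 and LOC103689992 with Rps9, and the counts of Tsen34 and Tsen34l1 were nearly equal. Members of such pairs share reads and are uncertain. The chi-square per gene between libraries was at least 6.8 in all 190 pairs, so that no pair agreed within sampling noise and each library counts as 1 replicate.

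Groups came from the treatment labels of the samples: water (H2O, n = 5), antibiotics (Abx, n = 4), short-chain fatty acids (SCFA, n = 6) and both (Abx_SCFA, n = 5). Replicate numbers only name libraries and pair nothing. The library titles, which were used to match the columns of the table, carry rat numbers. The H2O and Abx rats belong to the 2-hundred and 3-hundred number series and all SCFA and Abx_SCFA rats to the 4-hundred series. Number series and fatty acid treatment therefore cannot be told apart in the comparisons of SCFA or Abx_SCFA with H2O and of Abx_SCFA with Abx. Cage mates are not identified in the labels used here, so that rats of 1 cage were treated as separate.

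The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM scaling and 1 model of the 4 groups over all 20 libraries, which leaves 16 residual degrees of freedom. Genes were kept by filterByExpr, with a minimum of 10 counts in a library of median size and 15 counts in total, which left 12846 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values are counts scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2. The 6 contrasts were Abx, SCFA and Abx_SCFA against H2O, Abx_SCFA against Abx, Abx_SCFA against SCFA, and the interaction, which is Abx_SCFA minus SCFA less Abx minus H2O.

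Before the data were examined, 35 gene lists were fixed, covering neuronal, glial, vascular and neighbouring cell types, synaptic and receptor genes, immediate early genes, chromatin enzymes, fatty acid genes, immune genes and housekeeping pathways. The mitochondrially encoded list had 0 members in the table, so that 34 lists were tested. The test was camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists within a contrast. It was repeated with an estimated correlation and with fry. List scores are the mean log2 CPM of the members. An exact two-sided permutation of the scores between the libraries of both groups was added after the data were examined, with Benjamini-Hochberg adjustment over the 34 lists.

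The named genes followed a rule fixed before the data were examined. With fewer than 5 called genes in a contrast, it takes the called genes and the 5 genes with positive and the 5 with negative fold changes that have the smallest p, with a named symbol and a mean of at least 1 CPM. It also takes up to 4 members with the smallest p of each list that passed, and 14 genes whose levels are always given. To limit length, at most the first 2 members per list are printed, which was decided after the data were examined. A few genes that the rule takes are not reported here, and no other genes took their place.

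The effects of antibiotics in both backgrounds were correlated across genes as differences of group mean log2 CPM. Opposition was measured as the slope of Abx_SCFA less some Abx libraries on the remaining Abx libraries less H2O, averaged over splits of Abx into 2 and 2 libraries, so that no library was on both sides. Errors of both are jackknife standard errors over libraries.

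Library totals ranged from 17525358 to 25731636 counts. A count of 0 in 1 library allows up to 3 counts, or from 0.117 to 0.171 CPM depending on the library. Intervals and floors cover counting error only, because the reads carry no molecular identifiers.

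The procedure was tested on simulated counts with the means, library sizes and dispersions of these libraries and 200 changed genes among 12846. For Abx vs H2O, edgeR recovered 64 of 100 genes changed by 1.5 times and 85 of 100 changed by 2 times. For SCFA vs H2O it recovered 67 and 89, for Abx_SCFA vs H2O 70 and 85, for Abx_SCFA vs Abx 67 and 78, for Abx_SCFA vs SCFA 69 and 85, and for the interaction 46 and 67. Unchanged genes made up 6 of 155 calls, 14 of 170, 13 of 168, 8 of 153, 4 of 158 and 7 of 120 in the same order. For DESeq2, simulated for Abx vs H2O only, they made up 15 of 169. These values hold for 200 changed genes. The simulated genes varied independently of one another, unlike genes that follow tissue composition. In the simulation camera called the 1 raised list and 0 others.

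Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter on low counts (15474 genes), at least 10 counts in at least 10 libraries (12577 genes), only the groups of a comparison, an adjusted p below 0.1, an unadjusted p below 0.05, each library left out, the rat number series as a covariate, and the first surrogate variable of sva 3.50.0. Chosen after the data were examined were a covariate made of the cortical list score, the removal of SCFA replicates 2 and 5, the removal of H2O replicate 4 and Abx_SCFA replicate 5, and the exact permutation of list scores. SCFA replicates 2 and 5 were picked for their low Drd1. H2O replicate 4 and Abx_SCFA replicate 5 were picked because their Cend1 counts lay with those of SCFA. Calls of Cend1 and of genes that split the libraries alike therefore follow from that removal and give no separate support. Alternatives written for normalized values or for a deposited table of comparisons did not apply to counts.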

Results

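The transcriptome of the nucleus accumbens was profiled in 20 male rats that self-administered cocaine and drank water (H2O, n = 5), antibiotics that deplete the gut microbiome (Abx, n = 4), short-chain fatty acids, the fermentation products of gut bacteria (SCFA, n = 6), or antibiotics with short-chain fatty acids (Abx_SCFA, n = 5). Library totals ran from 18223766 to 22235777 counts in H2O, from 17525358 to 25366231 in Abx, from 17946132 to 25601695 in SCFA and from 18375538 to 25731636 in Abx_SCFA. All SCFA and Abx_SCFA rats carry numbers of another series than the H2O and Abx rats, so that number series and fatty acid treatment cannot be told apart in SCFA vs H2O, Abx_SCFA vs H2O and Abx_SCFA vs Abx.

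Markers of medium spiny neurons, the main neurons of the accumbens, were abundant in every group. Drd1, the D1 dopamine receptor, ran from 321 to 511 CPM in H2O (SD 69, n = 5), from 333 to 462 in Abx (SD 60.3, n = 4), from 171 to 411 in SCFA (SD 86.7, n = 6) and from 342 to 437 in Abx_SCFA (SD 35.8, n = 5). Drd2, the D2 dopamine receptor, had means of 210 ± 31, 214 ± 39, 171 ± 51.2 and 228 ± 14.3 CPM in the same order (SD). The opioid peptide precursor Pdyn stood at 440 ± 83.8, 421 ± 64.2, 343 ± 102 and 444 ± 51.5 CPM, and Penk at 1210 ± 184, 1160 ± 247, 934 ± 334 and 1250 ± 152 CPM. The histone deacetylase genes differed little between groups, with Hdac1 at 36.7 ± 4.04, 35.5 ± 1.76, 39.8 ± 5.63 and 35.4 ± 1.97 CPM and Hdac2 at 121 ± 8.2, 118 ± 6.99, 116 ± 8.48 and 116 ± 7.61 CPM. The activity-regulated genes Fos and Egr1 stood at 25.3 ± 6.33 and 109 ± 16.7 CPM in H2O, 35.8 ± 11.6 and 143 ± 23.6 in Abx, 35.6 ± 13.1 and 125 ± 41.9 in SCFA, and 30.2 ± 2.23 and 116 ± 13.8 in Abx_SCFA. Among glial genes, the astrocyte filament gene Gfap stood at 643 ± 124, 483 ± 80.9, 695 ± 124 and 576 ± 116 CPM, the microglial gene Aif1 at 16.8 ± 2.37, 16.0 ± 3.73, 17.5 ± 1.63 and 18.2 ± 2.64 CPM, and the myelin gene Mbp at 8220 ± 1700, 4970 ± 1440, 7490 ± 2950 and 7020 ± 1620 CPM. Ttr, a choroid plexus gene, had at most 5 counts in any library, near the limit that a count of 0 allows.

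Markers of cortical excitatory neurons, which lie outside the accumbens, varied strongly between libraries. Slc17a7, the vesicular glutamate transporter of cortical neurons, had a median of 14.6 CPM in H2O (range 3.09 to 252), 320 in Abx (43.7 to 506), 268 in SCFA (74 to 1060) and 194 in Abx_SCFA (132 to 339). Within H2O, replicate 5 had 252 CPM and the other libraries 3.09 to 32.8 CPM. Bdnf, a growth factor gene made by cortical neurons, stood at 1.51 ± 2.56, 9.93 ± 10.7, 14.6 ± 15.9 and 6.52 ± 2.98 CPM in the same order (SD). The cortical list score was 1.89 ± 1.1 in H2O, 3.61 ± 0.91 in Abx, 3.91 ± 1.2 in SCFA and 3.51 ± 0.42 in Abx_SCFA (mean log2 CPM, SD).

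**Figure D1:**
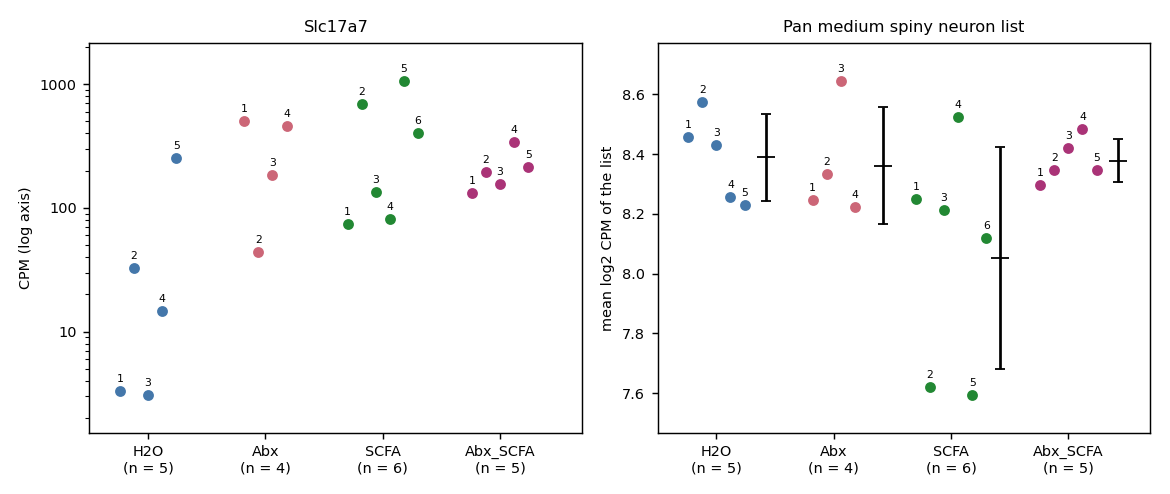
Slc17a7 in CPM on a log axis (left) and the mean log2 CPM of the pan medium spiny neuron list (right) in each library, by group. Points are libraries with their replicate numbers, and the bars on the right show the group mean and SD. Slc17a7 ran from 3.09 to 1060 CPM, and SCFA replicates 2 and 5 had the lowest spiny neuron scores.

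The comparison of Abx with H2O asks what depletion of the microbiome does to accumbens expression. The oligodendrocyte and myelin list was lower in Abx, with negative log2 fold changes in 26 of 26 members and a median of -0.66 (camera adjusted p = 9.6e-16). With an estimated correlation between genes, neither this list (adjusted p = 0.6) nor any of the other 14 called in this comparison passed (smallest 0.6). Enpp2 had a log2 fold change of -0.69 ± 0.24 (SE) and Aspa of -0.60 ± 0.22. The myelin score was 7.50 ± 0.47 in Abx (SD, n = 4) and 8.19 ± 0.24 in H2O (n = 5; exact permutation p = 0.00794, the smallest that 126 splits allow, and adjusted p = 0.18). Within SCFA alone the myelin score ran from 6.7 to 8.57, a wider span than the gap between the means of Abx and H2O. The lowest Abx library stood at 6.83. Libraries of the same treatment thus differed as much in myelin genes, and the cause was not tested. Blood genes had a median of -0.60, with Hba-a1, which may share reads with other haemoglobin genes, at -0.60 ± 0.24, and the interferon list a median of -0.24, with B2m, the light chain of class I MHC, at -0.36 ± 0.13 and the GTPase gene Gbp2 at -1.64 ± 0.64 (camera adjusted p = 0.002 for both lists). Without H2O replicate 1 the interferon list was not called (median -0.09, camera adjusted p = 0.56), and the value of Gbp2, Abx vs H2O, was -0.05. The inflammatory list had a median of -0.21 (camera adjusted p = 0.0018), with Lcn2 at -1.23 ± 0.39 and Tgfb1 at -0.30 ± 0.098, and the microglia list a median of -0.14 (0.0019), with the MHC class II chain gene Cd74 at -1.79 ± 0.53. The oligodendrocyte precursor list had a median of -0.20 (0.002), with Olig2 at -0.59 ± 0.18 and Olig1 at -0.48 ± 0.21. Ribosomal protein genes had a median of -0.11 over 81 members (2.1e-07), endothelial genes of -0.10 (0.015) and astrocyte genes of -0.06 (0.038), with the water channel gene Aqp4 at -0.30 ± 0.10. The astrocyte call was lost on removing any 1 of 6 libraries, the endothelial call any 1 of 3 and the blood call any 1 of 2. Removing 1 library ended the call of each of the ribosomal protein, inflammatory, microglia and oligodendrocyte precursor lists.

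On the higher side in Abx, the cortical excitatory neuron list had positive log2 fold changes in 14 of 14 members and a median of 1.75 (camera adjusted p = 6.1e-07), with the transcription factor genes Neurod6 at 2.47 ± 0.91 (SE) and Neurod1 at 3.09 ± 1.2. The immediate early and activity-regulated list was positive in 35 of 40 members, with a median of 0.15 (5.1e-06), and Bdnf and Nr4a2 at 2.70 ± 1.1 and 1.78 ± 0.75. The voltage-gated ion channel list had a median of 0.11 (5.1e-06), the presynaptic list of 0.18 (3.6e-05), the glutamate receptor list of 0.07 (0.002) and the cholesterol synthesis list of 0.09 (0.0039). The cholesterol call was lost on removing any 1 of 3 libraries and the glutamate receptor call on removing 1. Cacna1g, a calcium channel gene, had a log2 fold change of 1.14 ± 0.40 and Sv2a, a synaptic vesicle protein gene, of 0.21 ± 0.084.

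No single gene was called between Abx and H2O by edgeR, with 0 of 12846 genes at an adjusted p below 0.05, a smallest adjusted p of 0.563 and 1129 genes at an unadjusted p below 0.05 (419 higher and 710 lower). The count at an unadjusted p was 694 without H2O replicate 4, 626 without Abx replicate 3 and 630 without H2O replicate 4 and Abx_SCFA replicate 5. It was 1677 with quality weights and 1595 without SCFA replicates 2 and 5. DESeq2 called 1 gene, Tmed10, and limma-voom called 0. The genes with the smallest p, which did not pass, were on the lower side Tmed10, a vesicle trafficking gene (-0.26 ± 0.055, SE), the growth factor gene Tgfa (-0.69 ± 0.16), the ubiquitin ligase gene Itch (-0.29 ± 0.07), Ovol1 (-0.72 ± 0.18) and Galnt4 (-0.56 ± 0.14). On the higher side they were Mir671 (0.51 ± 0.13), Lrrfip1 (0.33 ± 0.087), the phosphodiesterase gene Pde4a (0.41 ± 0.11), Ptprs (0.33 ± 0.09) and the histone demethylase gene Kdm6b (0.35 ± 0.098). Counts at a microRNA symbol such as Mir671 may include reads of a host transcript. With the cortical score as a covariate, the immediate early list median turned to -0.09 and the presynaptic list to -0.02, and the cholesterol list was called as lower (-0.17, camera adjusted p = 9.8e-06). Lists not called without the covariate were called as higher, namely the pan medium spiny neuron and D2 neuron lists (0.27 and 0.33, 1.4e-08 and 0.00033), the striatal interneuron list (0.046) and the circadian clock list (0.035), and the myelin median was -0.43 (0.00025). The microglia (0.42), interferon (0.088), oligodendrocyte precursor (0.1), ribosomal protein (0.48), endothelial (0.37), astrocyte (0.42), glutamate receptor (0.2), immediate early (0.22), presynaptic (0.9) and cortical (0.87) lists were no longer called. The covariate is built from the cortical list, so that the loss of the cortical call with it, here and in later comparisons, was fixed in advance.

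**Figure D2:**
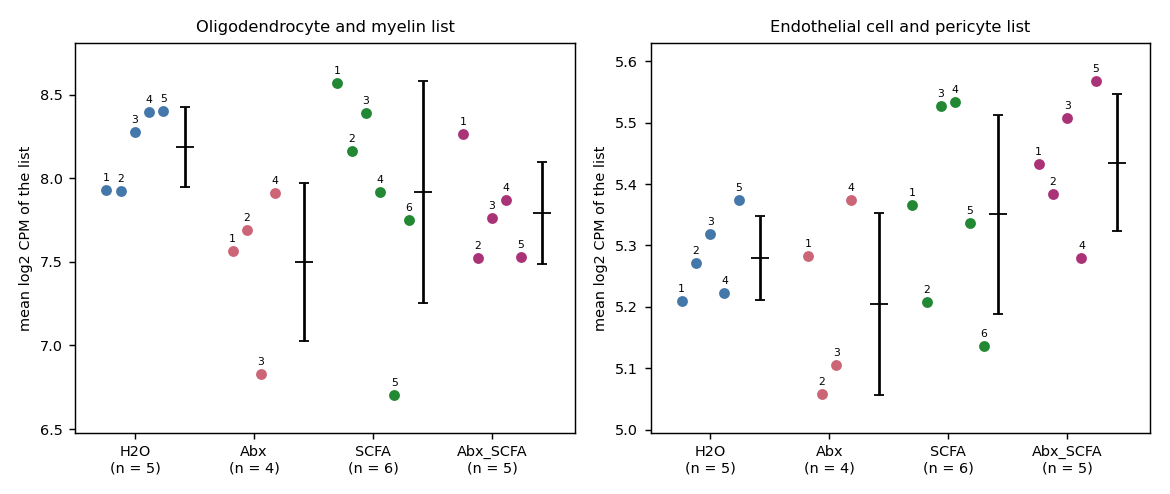
Mean log2 CPM of the oligodendrocyte and myelin list (left) and of the endothelial cell and pericyte list (right) in each library, by group. Points are libraries with their replicate numbers, and bars show the group mean and SD. The myelin score was 7.50 in Abx and 8.19 in H2O, and the endothelial score was 5.43 in Abx_SCFA and 5.21 in Abx.

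SCFA was compared with H2O to ask what the fatty acids do in rats with a normal microbiome. The pan medium spiny neuron list was lower in SCFA, with negative log2 fold changes in 25 of 25 members and a median of -0.29 (camera adjusted p = 2.9e-12), and the G protein gene Gnal and the phosphodiesterase gene Pde1c at -0.49 ± 0.16 and -0.52 ± 0.17 (SE). The score of this list ran from 7.59 to 8.52 in SCFA, lowest in replicates 2 and 5, and from 8.23 to 8.58 in H2O. With an estimated correlation, neither this list (adjusted p = 0.78) nor any of the other 10 called here passed (smallest 0.78). The D1 neuron list had a median of -0.34 (0.0032), with Drd1 at -0.50 ± 0.17 and the transcription factor gene Isl1 at -0.71 ± 0.25, and 2 members passing when adjusted over the list alone, and the D2 neuron list a median of -0.30 (0.005), with Ptprm at -0.28 ± 0.099. The myelin list had a median of -0.18 (0.0022), a call lost on removing any 1 of 2 libraries. The GABA receptor list had a median of -0.16 (0.033) but a mean of 0.0054, with Gabra4 at -0.31 ± 0.11 and Gabbr2 at 0.98 ± 0.35. Its call was lost on removing any 1 of 3 libraries. The cortical list was positive in 14 of 14 members, with a median of 2.36 (1.8e-08). Adjusted over the list alone, 13 of its members passed, against 0 over all genes. Neurod1 and Fezf2 stood at 4.16 ± 1.1 and 1.34 ± 0.41.

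Cholesterol synthesis genes were higher in SCFA in 24 of 24 members, with a median of 0.23 (camera adjusted p = 8.3e-08), and Sqle at 0.34 ± 0.10 (SE). The immediate early list had a median of 0.19 (1.3e-05), with Bdnf at 3.24 ± 1.0 and Nptx2 at 1.02 ± 0.34. The heat shock list had a median of 0.08 (0.033), with the stress factor genes Ddit3 at 0.32 ± 0.093 and Atf4 at 0.35 ± 0.11. The extracellular matrix list had a median of 0.11 (0.037), with Tnc at 1.15 ± 0.40, and the ependymal list one of 0.50 (0.046), although Tekt1, its member with the smallest p, stood at -0.43 ± 0.19. The ependymal call was lost on removing any 1 of 14 of the 20 libraries, that of the extracellular matrix list any 1 of 5 and that of the heat shock list any 1 of 4. Slc17a7 was highest, and Drd1 lowest, in SCFA replicates 2 and 5.

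edgeR called 0 genes between SCFA and H2O, with a smallest adjusted p of 0.247 and 1770 genes at an unadjusted p below 0.05 (1053 higher and 717 lower). DESeq2 called 10 and limma-voom 0. The count at an unadjusted p was 2328 without H2O replicate 5, 2253 without SCFA replicate 4 and 2078 without SCFA replicate 1. The falls under the next settings are not separate checks. Without SCFA replicates 2 and 5, which had the highest Slc17a7 and were picked after the data were examined, the count was 636. It was 374 with the first surrogate variable, whose correlation with the cortical score was 0.97, and 442 with the cortical score as a covariate. With that covariate the immediate early, cholesterol, myelin, D2 neuron and cortical list medians changed sign, while the pan medium spiny neuron list (median -0.00064, camera adjusted p = 0.9) and the D1 neuron list (-0.04, 0.28) were not called, nor the ependymal (0.069), heat shock (0.069) and extracellular matrix (0.4) lists, and the cholesterol and immediate early lists were called as lower (0.00096 and 0.005). Newly called with it were the presynaptic list as lower (-0.15, 7e-07) and the ribosomal protein and endothelial lists as higher (0.10 and 0.09, 7e-07 and 0.0051), and the GABA receptor list stayed lower (0.00096). Not passing, with the smallest p, were Cend1, a neuronal cell cycle exit gene (-3.52 ± 0.67, SE), RragB, which encodes a Rag GTPase (-2.33 ± 0.52), Mid2 (-0.42 ± 0.081), Erlin1 (-0.32 ± 0.07) and the potassium channel gene Kcns2 (-0.32 ± 0.075), and on the higher side Ahnak (0.27 ± 0.061), Fkbp10 (0.38 ± 0.091), the orexin receptor gene Hcrtr1 (1.56 ± 0.37), Cks1b (0.61 ± 0.15) and Gtse1 (0.64 ± 0.16). Cend1 had 4 to 14 counts in the 6 SCFA libraries, but also 7 in H2O replicate 4 and 8 in Abx_SCFA replicate 5, against 88 to 240 in the other 12 libraries. Without H2O replicate 4, or without both these libraries, edgeR called 2 genes, Cend1 and RragB, and without Abx_SCFA replicate 5 it called 1, Cend1. Both libraries were picked for these Cend1 counts, so that the calls made without both follow from that choice.

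**Figure D3:**
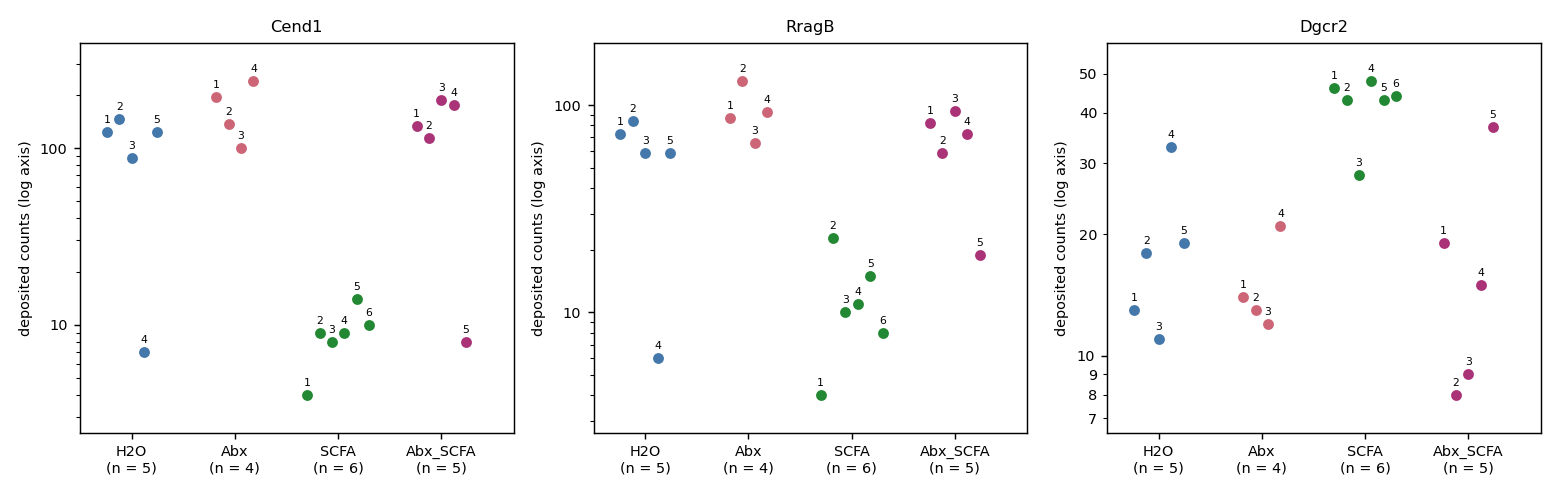
Deposited counts of Cend1, RragB and Dgcr2 on log axes in each library, by group. Points are libraries with their replicate numbers. H2O replicate 4 and Abx_SCFA replicate 5 lie with the 6 SCFA libraries for all 3 genes, and Cend1 had 4 to 14 counts in these 8 libraries and 88 to 240 in the other 12.

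For rats given both treatments, Abx_SCFA against H2O, endothelial and pericyte genes were higher in 27 of 29 members, with a median of 0.14 (camera adjusted p = 1.9e-06), Esam at 0.21 ± 0.088 (SE) and the smooth muscle gene Tagln at 0.50 ± 0.21. With an estimated correlation, neither this list (adjusted p = 0.96) nor any of the other 6 called here passed (smallest 0.96). The myelin list was negative in 26 of 26 members, with a median of -0.38 (2.8e-07) and Enpp2 at -0.48 ± 0.22. The cortical list had a median of 1.37 (6.3e-06), and the immediate early list one of 0.11 (0.00015), with the neuropeptide precursor gene Vgf at 0.49 ± 0.11 and 1 member passing when adjusted over the list alone. The meninges list had a median of 0.16 (0.029), with the matrix gene Dcn at 0.28 ± 0.13, and oxidative phosphorylation genes one of 0.03 (0.019), with Cox6a1 at 0.19 ± 0.073. The meninges call was lost on removing any 1 of 4 libraries, and the oxidative phosphorylation and interferon calls any 1 of 5. The interferon list had a median of -0.27 (0.029), with Isg15 at -0.64 ± 0.19 and Gbp2 at -1.42 ± 0.58. Without H2O replicate 1 the interferon median was 0.03 and Gbp2 stood at 0.18. Without H2O replicate 2, 11 lists were called in place of 7.

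Between Abx_SCFA and H2O, edgeR called 0 genes, with a smallest adjusted p of 0.815 and 714 genes at an unadjusted p below 0.05 (269 higher and 445 lower). The count at an unadjusted p was 438 without H2O replicate 4, 419 without Abx_SCFA replicate 5, 266 without both and 1174 without H2O replicate 5. It was 2061 with quality weights, 1145 with only the groups of the comparison and 1075 with the cortical score as a covariate. With that covariate the pan medium spiny neuron, D2 neuron, ribosomal protein and septal and deep nuclei lists were called as higher (camera adjusted p = 7.4e-10, 6.1e-05, 0.00037 and 0.034) and the cholesterol, presynaptic and immediate early lists as lower (5.7e-10, 0.011 and 0.023). The myelin list (median -0.19, 0.37) and the interferon list (0.32) were then not called, nor was the cortical list from which the covariate is built (0.95). DESeq2 called 1, Rgcc, and limma-voom 0. The smallest p on the higher side, not passing, belonged to Rgcc, a cell cycle regulator (0.39 ± 0.079, SE), Vgf, Tpm2 (0.44 ± 0.11), the riboflavin transporter gene Slc52a3 (0.57 ± 0.16) and Mir3542 (0.40 ± 0.11), whose counts may include a host transcript, and on the lower side to the exonuclease gene Xrn1 (-0.30 ± 0.065), Ptar1 (-0.46 ± 0.10), Nkain3 (-0.59 ± 0.15) and Cetn4 (-0.51 ± 0.13).

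Abx_SCFA and Abx were compared to see what the fatty acids add in rats given antibiotics. Endothelial and pericyte genes were higher in Abx_SCFA in 29 of 29 members, with a median of 0.25 (camera adjusted p = 2.5e-17), and 3 members passed when adjusted over the list alone, against 0 over all genes. Neither this list (adjusted p = 0.3) nor any of the other 10 called here passed with an estimated correlation (smallest 0.3). Cldn5, a tight junction gene of the blood-brain barrier, stood at 0.43 ± 0.11 (SE), and the glucose transporter gene Slc2a1 at 0.25 ± 0.07. The endothelial score was 5.43 ± 0.11 in Abx_SCFA (SD, n = 5) and 5.21 ± 0.15 in Abx (n = 4; exact permutation p = 0.0397, adjusted p = 0.54). Blood genes had a median of 0.63 (1e-06), with the haemoglobin genes Hbb at 0.77 ± 0.28 and Hba2 at 0.70 ± 0.28. Ribosomal protein genes were higher in 71 of 81 members, with a median of 0.10 (8.8e-11) and Rpl30 at 0.34 ± 0.10. Their call was lost on removing 1 of the 20 libraries. The myelin list was higher in 26 of 26 members, with a median of 0.24 (2e-05) and Mbp at 0.50 ± 0.29, a call lost on removing 1 of the 20 libraries. The meninges list had a median of 0.14 (0.0019), the inflammatory list of 0.13 (0.0023), with Tgfb1 at 0.30 ± 0.097, the microglia list of 0.11 (0.0055) and the astrocyte list of 0.07 (0.044), a call lost on removing any 1 of 13 libraries. Lower in Abx_SCFA were voltage-gated ion channel genes, with a median of -0.13 (1.1e-06) and the sodium channel gene Scn1a at -0.36 ± 0.10, presynaptic genes at -0.10 (0.0017) and glutamate receptor genes at -0.05 (0.013).

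For this comparison edgeR called 0 genes, with a smallest adjusted p of 0.999 and 410 genes at an unadjusted p below 0.05 (238 higher and 172 lower). The count at an unadjusted p was 689 without Abx replicate 1, 617 without Abx_SCFA replicate 2, 247 without Abx_SCFA replicate 5, 230 without H2O replicate 4 and Abx_SCFA replicate 5, and 842 with quality weights. With the cortical score as a covariate it was 509, of which 393 were shared with the 410. Every list called here except the astrocyte list (camera adjusted p = 0.054) stayed called with that covariate. DESeq2 and limma-voom called 0 each. Genes with the smallest p, which did not pass, were on the higher side Tll2 (0.98 ± 0.23, SE), Tnfsf12 (0.40 ± 0.094), Tmem243 (0.34 ± 0.083), Cldn5 and the parathyroid hormone receptor gene Pth1r (0.39 ± 0.11), and on the lower side Ero1b (-0.33 ± 0.083), Scn1a, Tnik (-0.21 ± 0.061), Ap4e1 (-0.27 ± 0.081) and Cetn4 (-0.44 ± 0.14).

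Within the rats given short-chain fatty acids, Abx_SCFA was compared with SCFA. Medium spiny neuron lists were higher in Abx_SCFA: the pan list in 25 of 25 members with a median of 0.28 (camera adjusted p = 3e-16), the D2 list with 0.39 (5.2e-06) and the D1 list with 0.37 (9.7e-05). The pan score ran from 7.59 to 8.52 in SCFA, lowest in replicates 2 and 5, and from 8.3 to 8.48 in Abx_SCFA. The pan list did not pass with an estimated correlation (adjusted p = 0.37), nor did any of the other 9 called here (smallest 0.36). Drd2 stood at 0.41 ± 0.17 (SE), Drd1 at 0.40 ± 0.17, Gnal at 0.38 ± 0.16 and Tmem158 at 0.47 ± 0.17. The list of dopamine signalling and cocaine response genes had a median of 0.05 (0.0019), with the protein kinase A subunit gene Prkar2b at 0.26 ± 0.10, the oxidative phosphorylation list one of 0.03 (0.0015) and the endothelial list one of 0.08 (0.0028). The oxidative phosphorylation call was lost on removing any 1 of 2 libraries and the endothelial call any 1 of 3. Lower were ependymal genes, with a median of -0.90 (6.9e-05), the ciliary regulator gene Foxj1 at -1.02 ± 0.36 and Ccdc153 at -1.15 ± 0.41, with 3 members passing when adjusted over the list alone. Cholesterol synthesis genes had a median of -0.16 (5.2e-06), with Sqle at -0.28 ± 0.10 and Idi1 at -0.35 ± 0.14. The heat shock list had a median of -0.07 (0.02), a call lost on removing any 1 of 4 libraries. The cortical list had a median of -0.84 (0.025), and 0.22 without SCFA replicates 2 and 5. These replicates had the highest Slc17a7, so that a rise of this median on their removal follows from the choice. Without SCFA replicate 5, 16 lists were called in place of 10, and the cortical call was lost on removing any 1 of 5 libraries. With the cortical score as a covariate every list called here stayed called except the cortical list, from which the score is built (camera adjusted p = 0.46). The pan, D2 and D1 medians were then 0.24, 0.36 and 0.34 (2.2e-16, 2e-06 and 4e-05). The myelin, oligodendrocyte precursor and presynaptic lists were newly called (0.0082, 0.018 and 0.04).

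No gene was called between Abx_SCFA and SCFA by edgeR, with a smallest adjusted p of 0.285 and 871 genes at an unadjusted p below 0.05 (349 higher and 522 lower). The unadjusted count was 480 without SCFA replicate 2, 470 without SCFA replicates 2 and 5, 1535 without SCFA replicate 4 and 561 without Abx_SCFA replicate 3. DESeq2 called 3, Cend1, RragB and Dgcr2, and limma-voom 0. The smallest p on the higher side, not passing, belonged to Cend1 (3.76 ± 0.67, SE), RragB (2.43 ± 0.52), Rps9 (0.91 ± 0.20) and Tsen34 with Tsen34l1 (2.48 ± 0.64 each), and on the lower side to Dgcr2 (-1.35 ± 0.29), Nectin3 (-0.43 ± 0.11), Gtse1 (-0.58 ± 0.16), Zbtb44 (-0.32 ± 0.088) and the endothelin receptor gene Ednra (-0.43 ± 0.12). Rps9, Tsen34 and Tsen34l1 share their counts with another symbol. Without H2O replicate 4, edgeR called Cend1 and RragB (2 genes), and without Abx_SCFA replicate 5 it called Cend1 (1 gene). Without both libraries it called 5 genes, Cend1, RragB, Dgcr2, Tsen34 and Tsen34l1. Both were picked for their low Cend1 counts, so that calls of genes with the same split follow from that choice.

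Whether the antibiotic effect differs with short-chain fatty acids was tested by the interaction. Camera called 15 lists, led by the cortical list with a median of -2.73 (adjusted p = 4.8e-08) and 8 members passing when adjusted over the list alone, the pan medium spiny neuron list with 0.29 (1.1e-07), the cholesterol list with -0.30 (2.2e-07) and the myelin list with 0.44 (3.3e-07). Members of these lists included Neurod1 at -4.59 ± 1.4 (SE), Pde1c at 0.62 ± 0.25 and Mbp at 0.63 ± 0.39. In immune lists, Cd74 stood at 2.02 ± 0.70 and Lcn2 at 1.5 ± 0.53. With an estimated correlation 0 lists passed (smallest adjusted p = 0.69), and with the cortical score as a covariate 4 lists were called, the inflammatory, endothelial, ependymal and blood lists. None of the 4 leading lists was among them, with medians of 0.07 for the cortical list, -0.01 for the pan medium spiny neuron list, 0.03 for the cholesterol list and 0.19 for the myelin list (camera adjusted p = 0.98, 0.98, 0.19 and 0.18). The outcome for the cortical list was fixed in advance, because the covariate is built from it.

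The interaction gave 0 called genes by edgeR, DESeq2 and limma-voom, with a smallest edgeR adjusted p of 0.622 and 1008 genes at an unadjusted p below 0.05 (364 higher and 644 lower). The count at an unadjusted p was 489 with the cortical score as a covariate, 419 with the first surrogate variable and 498 without SCFA replicates 2 and 5. As in SCFA vs H2O, these settings overlap and are not separate checks. The count was 1423 without H2O replicate 5, 1417 without SCFA replicate 1 and 1382 without SCFA replicate 4. Not passing, with the smallest p, were Tll2 (1.27 ± 0.31, SE), the fucosyltransferase gene Fut8 (0.38 ± 0.10), Ddx28 (0.45 ± 0.12), Gskip (0.36 ± 0.097) and Tnfsf12 (0.46 ± 0.13) on the higher side, and Kdm6b (-0.50 ± 0.13), Mst1r (-1.60 ± 0.44), the neuropeptide gene Cort (-2.59 ± 0.73), Rasa2 (-0.29 ± 0.083) and Osbpl6 (-0.45 ± 0.13) on the lower side. Without H2O replicate 4 and Abx_SCFA replicate 5, edgeR called 1 gene, Cend1, a call that follows from picking these libraries for their Cend1 counts.

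Across 12846 genes, which are not independent replicates, the antibiotic effects without and with short-chain fatty acids had a Pearson correlation of -0.16 ± 0.35 (jackknife SE), with the same sign in 49.4% of genes. The correlation was 0.09 without SCFA replicate 5. The opposition slope was -0.06 ± 0.12 (jackknife SE). In simulated counts it was -0.39 with an antibiotic effect planted in Abx alone and 0.00063 with the effect in both antibiotic groups, values that depend on the sizes planted. Neither value differed from 0 by more than its error.

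Camera without a covariate called 9 lists in none of the 6 comparisons. Genes of histone deacetylases and acetyltransferases had medians between -0.03 and 0.02 (smallest camera adjusted p = 0.22), genes of DNA and histone methylation between -0.04 and 0.0023 (0.16), and genes of short-chain fatty acid receptors, transport and metabolism between -0.03 and 0.01 (0.85). Striatal interneuron genes lay between -0.15 and 0.11 (0.066), but their score was higher than in H2O by 0.34 in Abx, 0.32 in SCFA and 0.32 in Abx_SCFA (exact permutation p = 0.0159, 0.00649 and 0.00794, adjusted p = 0.18, 0.221 and 0.216). Medians of septal and other deep nuclei genes lay between -0.0059 and 0.21 (0.13), and choroid plexus genes between -0.15 and 0.14 (0.56). Circadian clock genes lay between -0.06 and 0.08 (0.1), glucocorticoid response genes between -0.09 and 0.09 (0.24), and ubiquitin and proteasome genes between -0.01 and 0.03 (0.1). Random reassignment of the 20 libraries to the 4 groups gave a median of 11 or 12 called lists per comparison, against 7 to 15 with the real groups, so that the number of called lists lies within what chance gives.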

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

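The tests of explanations in this part, and the counts over other splits, were all chosen after the results they address were seen. Of 120 groups of libraries examined for a library far from the others, 5 had one, and chance gives about 1 in 20. Slc17a7 in H2O replicate 5 stood at 252 CPM, with the next library at 32.8 CPM. Bdnf in the same library stood at 6.05 CPM, with the next at 0.906 CPM. Gfap in the same library stood at 860 CPM, with the next at 630 CPM. Gfap in Abx replicate 2 stood at 362 CPM, with the nearest library at 520 CPM. The striatal interneuron score of Abx_SCFA replicate 1 was 3.94, with the nearest library at 4.11.

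Camera on the interaction called 15 lists, and 0 lists were called with an estimated correlation or with fry. Other splits of the libraries gave a median of 12 called lists in the interaction and at most 22, so that 15 lies within what chance gives. The median interaction was negative for the cortical list (-2.73), the ependymal list (-0.93), the cholesterol list (-0.30), the immediate early list (-0.29), the presynaptic list (-0.18) and the ion channel list (-0.16). It was positive for the blood list (0.60), the D1 neuron list (0.44), the myelin list (0.44), the D2 neuron list (0.41), the pan medium spiny neuron list (0.29), the inflammatory list (0.20), the microglia list (0.17), the endothelial list (0.17) and the ribosomal protein list (0.096).

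Cortical excitatory neuron markers were higher on average in the 3 treated groups than in H2O. Adjoining cortical tissue in the dissected samples would lower the spiny neuron score where the cortical score is high, and within groups Pearson's r was -0.685 (Spearman's rho -0.66, permutation p = 0.0095 and 0.013, 4 relations computed, 20 libraries). Without H2O replicate 5 and SCFA replicate 5, r was -0.58, and among the 11 libraries of the 4-hundred number series it was -0.83 (rho -0.7, permutation p = 0.023 and 0.065), while the other series hold 4 and 5 libraries, too few for a value. The relation rests on the SCFA libraries, with r of -0.92 in these (rho -0.94, exact permutation p = 0.011 and 0.017, 6 libraries) and -0.36 in the other 3 groups (rho -0.43, permutation p = 0.32 and 0.2, 14 libraries). In Abx_SCFA the library with the highest cortical score (4.10) also had the highest spiny neuron score (8.48). A treatment that raises the markers also stays open. Of the variance of the cortical score, 46% lay between groups (permutation p = 0.016). That share restates the pattern, and tissue amounts or number series that differ between groups would give it too. Differing amounts of cortical tissue may account for the pattern in SCFA, with less support in the other groups. These data do not decide between that, treatment and, for SCFA and Abx_SCFA, number series.

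With the cortical score as a covariate, the genes at an unadjusted p below 0.05 in SCFA vs H2O went from 1770 to 442, of which 109 were shared, against 642 that 5% of the genes tested would give. The median size of the 1770 fold changes was 0.36 on the log2 scale without the covariate. With it their median was 0.064, taken in the direction each had without it, so that changes that turned count as negative. The median SE was 0.137 before and after. These genes were picked for a small p without the covariate, so that some fall follows from that choice. Computed alike, the medians were 0.327 and 0.223 in Abx vs H2O and 0.231 and 0.178 in Abx_SCFA vs H2O. In the interaction the count went from 1008 to 489, and the medians computed alike were 0.584 and 0.191. In Abx vs H2O the count went from 1129 to 1188, of which 272 were shared, and in Abx_SCFA vs H2O from 714 to 1075, of which 212 were shared, although the cortical list was higher there too. A cortical share that differs between libraries may therefore account for much of the count in SCFA vs H2O, while the counts of Abx vs H2O and Abx_SCFA vs H2O did not fall. Most genes behind these last counts were not shared, so that they too depended on the covariate. Because the score also differed between the groups, the covariate would remove an effect of treatment that runs along with it.

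Cend1, RragB, Tsen34 and Dgcr2 stood at another level in the SCFA libraries. In the 6 SCFA libraries, H2O replicate 4 and Abx_SCFA replicate 5, Cend1 had 4 to 14 counts, RragB 4 to 23, Tsen34 4 to 39 and Dgcr2 28 to 48. In the other 12 libraries they had 88 to 240, 59 to 131, 55 to 155 and 8 to 21. Short-chain fatty acids in the drinking water as the whole cause are argued against by 5 libraries whose Cend1 count lies on the other side of the gap than their treatment. These are H2O replicate 4 (7 counts) and Abx_SCFA replicates 1 to 4 (114 to 188 counts). The latter also received antibiotics, so that only H2O replicate 4 departs without that difference. The gap was drawn at the highest SCFA count, so that no SCFA library could depart. Reads assigned differently between neighbouring genes cannot be told apart from other causes. Of 16 neighbours, the nearest 2 tested on each side in GRCr8, 0 separated these libraries. Moved reads could not show in neighbours with many counts, such as Ap2a2 (6253 to 10845 in SCFA) or Ubqln2 (5155 to 6798). Dropped reads need not show in any neighbour. Rplp2, a ribosomal protein gene beside Cend1, had only 5 to 21 counts in SCFA, where the ribosomal protein list had a mean score of 6.91 log2 CPM. Reads may therefore be missing at that locus, which was not tested. Rps9, beside Tsen34, was lower in SCFA as well (14 to 24 counts), but had 40 in H2O replicate 4 and 46 in Abx_SCFA replicate 5. An unrecorded library batch or a genetic variant was not tested.

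Chance cannot be excluded for any count over the 100 splits of the 20 libraries into groups of the same sizes, the real groups being counted as 1 of the 100. As many genes at an unadjusted p below 0.05 came from 14 splits for Abx vs H2O (1129, highest other 2451), 5 for SCFA vs H2O (1770, 2467; 4 of them other than the real groups, at the limit of 5%), 38 for Abx_SCFA vs H2O (714, 2761), 67 for Abx_SCFA vs Abx (410, 3078), 33 for Abx_SCFA vs SCFA (871, 2474) and 26 for the interaction (1008, 3249). As many called lists came from 22 splits for Abx vs H2O (15, highest other 22), 60 for SCFA vs H2O (11, 22), 93 for Abx_SCFA vs H2O (7, 22), 70 for Abx_SCFA vs Abx (11, 20), 79 for Abx_SCFA vs SCFA (10, 21) and 23 for the interaction (15, 22). A correlation of antibiotic effects as far from 0 came from 46 splits (highest other 0.55), and an opposition slope as low from 34 (lowest other -0.62). Between 1 and 4 other splits called genes in a comparison, up to 293, 246, 570, 678, 178 and 860 in the 6 comparisons, against 0 with the real groups, and the cause was not tested.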

How the results depend on the processing

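The cortical score covariate, the removal of pairs of libraries and the exact permutation of list scores were chosen after the data were examined, and the cause of each change below was not tested unless it is named. The count of called genes was 0 in all 6 comparisons with RLE scaling, limma-voom with and without quality weights, both filter alternatives, an adjusted p below 0.1, the first surrogate variable, the cortical score and without SCFA replicates 2 and 5. It was also 0 with only the groups of a comparison and with the number series, where these could be fitted. RLE scaling moved the median of all genes by at most 0.01 on the log2 scale. No paired analysis was possible because replicate numbers give only the order of the libraries. The number series could not be fitted in SCFA vs H2O, Abx_SCFA vs H2O and Abx_SCFA vs Abx, and the interaction needs all groups. Alternatives for normalized values or a deposited table of comparisons did not apply. Of the values of single genes, 5917 kept direction and side of the threshold, 25 passed it and 13 changed sign. Of the values of single lists, 1933 kept both, 200 lost the call and 31 changed sign. Of the 69 list calls, leaving out 1 library lost from 1 (SCFA replicate 1) to 15 (H2O replicate 5), most often those of the ependymal list in SCFA vs H2O (14 of 20 libraries) and the astrocyte list in Abx_SCFA vs Abx (13 of 20).

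DESeq2 called 1 gene in Abx vs H2O, 10 in SCFA vs H2O, 1 in Abx_SCFA vs H2O and 3 in Abx_SCFA vs SCFA. At an unadjusted p below 0.05 the counts were 1129 for Abx vs H2O, 1770 for SCFA vs H2O, 714 for Abx_SCFA vs H2O, 410 for Abx_SCFA vs Abx, 871 for Abx_SCFA vs SCFA and 1008 for the interaction, by the construction of a looser threshold. Without H2O replicate 4 and Abx_SCFA replicate 5, genes called were 2 in SCFA vs H2O, 5 in Abx_SCFA vs SCFA and 1 in the interaction, and gene lists called were 13 in Abx_SCFA vs H2O. These libraries were picked for their Cend1 counts, so that the gene calls follow from that choice. With the first surrogate variable, whose correlation with the cortical score was 0.97, lists called were 4 in SCFA vs H2O, 11 in Abx_SCFA vs H2O and 3 in the interaction. With the cortical score they were 9 in Abx vs H2O, 6 in SCFA vs H2O and 4 in the interaction. With an estimated correlation and with fry, 0 lists were called in Abx vs H2O, SCFA vs H2O, Abx_SCFA vs H2O, Abx_SCFA vs Abx, Abx_SCFA vs SCFA and the interaction, and so 0 of 69 overall. With exact permutation of list scores 0 were called in each of the 5 comparisons of groups, which says little. The smallest p possible was 0.0079 in Abx vs H2O, Abx_SCFA vs H2O and Abx_SCFA vs Abx and 0.0022 in SCFA vs H2O and Abx_SCFA vs SCFA, so that no list could pass the adjustment over 34 lists on its own.

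Leaving out each library in turn, genes called ranged from 0 to 2 in SCFA vs H2O and in Abx_SCFA vs SCFA, and were 0 in the other comparisons. Lists called ranged from 10 to 16 in Abx vs H2O, 8 to 12 in SCFA vs H2O, 5 to 11 in Abx_SCFA vs H2O, 9 to 16 in Abx_SCFA vs Abx, 8 to 16 in Abx_SCFA vs SCFA and 12 to 18 in the interaction, and from 57 to 74 in all. The correlation of antibiotic effects ranged from -0.29 to 0.092 and was 0.14 with the cortical score removed. The opposition slope ranged from -0.12 to 0.015, the latter without Abx replicate 3.

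These medians changed sign with the first surrogate variable and then with the cortical score. In Abx vs H2O the immediate early list went to -0.026 and -0.095, the presynaptic list to -0.0030 and -0.025 and the cholesterol list to -0.088 and -0.17. In SCFA vs H2O the immediate early list went to -0.061 and -0.14, the D2 neuron list to 0.017 and 0.043, the myelin list to 0.042 and 0.041 and the cholesterol list to -0.045 and -0.090. In Abx_SCFA vs H2O the immediate early list went to -0.037 and -0.13. In Abx_SCFA vs SCFA the cortical list went to 0.29 and 0.11, and to 0.22 without SCFA replicates 2 and 5, which had the highest Slc17a7. In the interaction the immediate early list went to 0.0081 and 0.082 and the presynaptic list to 0.052 and 0.078. With the cortical score alone, the cortical list, from which the score is built, went to -0.020 in SCFA vs H2O, -0.067 in Abx_SCFA vs H2O and 0.066 in the interaction. In the interaction it also turned the D2 neuron list to -0.015, the pan medium spiny neuron list to -0.012, the ribosomal protein list to -0.019 and the cholesterol list to 0.035. In Abx_SCFA vs H2O, leaving out each library in turn, the interferon median ranged from -0.37 to 0.028 and the value of Gbp2, Abx_SCFA vs H2O, from -1.66 to 0.18, both highest without H2O replicate 1.

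Among single genes, with the first surrogate variable and then the cortical score, in SCFA vs H2O Nptx2 went to -0.063 and -0.24, Gabbr2 to -0.21 and -0.38 and Hapln4 to -0.16 and -0.28. With the cortical score alone, in SCFA vs H2O Isl1 went to 0.0036, Gpr6 to 0.027, Fezf2 to -0.047 and Atf4 to -0.039, and in the interaction Bdnf went to 0.0020 and Acat2 to 0.0025. Depth limits genes such as Ttr, with at most 5 counts in a library.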

Other observations

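Some members of lists that camera did not call passed when adjusted over the list alone, against 0 over all genes. In SCFA vs H2O these were 4 of 14 striatal interneuron genes, 4 of 20 genes of septal and other deep nuclei, 3 presynaptic genes, 2 circadian genes, and 1 each of the DNA and histone methylation, interferon and dopamine signalling lists. In the interaction they were 3 circadian genes and 1 methylation gene, in Abx vs H2O 1 methylation gene, and in Abx_SCFA vs SCFA 1 ribosomal protein gene. These counts were examined after the data were seen and are not adjusted over the lists. The circadian genes counted in SCFA vs H2O and in the interaction include Rorb, which is also a member of the cortical list. All were counted without the cortical score as a covariate. With it, the genes at an unadjusted p below 0.05 in SCFA vs H2O went from 1770 to 442.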
